A study of Homo sapiens with 9 samples.

How the data were processed

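Total RNA of 9 SW480 samples was hybridised to Agilent gene expression arrays according to the design text, 1 array per sample and in 1 colour per the file headers. Each array's deposited scanner table gives a spot intensity, the processed signal in linear units, which Agilent Feature Extraction 11.5.1.1 produced by background subtraction, per the file headers. The series table deposited by the authors holds log2 values, and set against the scanner values it equals the log2 processed signal minus 1 constant per array for 100% of probes within 0.01. Its column medians run from -3.99 to -3.74, and its 75th percentiles from 0.00395 to 0.00798. It is therefore scaled almost as the main values described below, and results from it are no separate check of the scaling. Groups and replicate numbers were taken from the sample titles, which number the samples of each group as experiments 1 to 3. Nothing in the labels says that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

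Of 62976 spots per array, control spots were left out, spots with an outlier mark were dropped, and spots of 1 probe were averaged, which gave 50599 probes. No spot was saturated. The main values were log2 of the processed signal minus each array's 75th percentile. A probe was kept if it was well above background on all 3 arrays of at least 1 group, and 17 probes without a usable value on some arrays were left out, which left 27530 probes, 24271 of them above background on all 9 arrays. The files give accessions but no current symbols, so names came from NCBI's RefSeq table of assembly GRCh38.p14 by unversioned accession. Of the 50599 probes 30275 received a symbol and 20324 kept the name in the file. The array design refers to another build, so no coordinates are given. For a gene with several probes the one with the highest mean signal was used, which gave 21722 genes, 15360 with a symbol and 4408 with several probes.

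Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 9 samples with a mean per group), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors are standard errors of the fitted log2 difference with n = 3 and 3. A probe not above background on any array of a group has only a bound there. Its fold is written "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. No fold is given where neither group had an array above background or where the bound was not above 1. The number of arrays limits the precision.

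Gene lists, 35 of them, were tested with camera at a preset correlation of 0.01, where a list had at least 3 tested genes, and their p-values were adjusted over the lists. They include lists of fibroblast, leukocyte, endothelial and erythroid markers. The same tests were run with an estimated correlation, and fry, which asks only whether a list's genes move one way, was run as a further alternative. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes every probe of POU5F1, KLF4 and SOX2. It adds the 10 largest rises and falls past the test with a gene symbol, the brighter group above background on all 3 arrays and all 3 samples of one group beyond the other 3. It also takes up to 4 called members of each called list, and up to 4 of the stem cell, ABC transporter, pluripotency and Wnt lists. CDX2, VIL1, HNF4A, CLDN3, BNIP3 and SLC30A1 were named beyond the rule and chosen after their values were seen.

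Samples with the same number deviated together in the 2 OKS groups. The correlations across genes of their deviations from the group means were 0.431, 0.453 and 0.291. The highest value between other numbers was -0.051, but deviations cancel within a group, so positive values for equal numbers force lower ones elsewhere. The numbers were read as pairing those 2 groups. In pairs 1 and 2 both arrays lay in the same row of slide 1, so array position could also give their correlation. The arrays of pair 3 lay on different slides. Against Mock the correlations of samples with the same number ran from -0.234 to 0.047, and the numbers were not read as pairs. A fit with replicate number as a block was run throughout, and 1 with only the 2 OKS groups was added after this check.

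Because both OKS groups share the Mock arrays, 50 simulations of 3 unchanged groups were made, with 1 simulated control group for both comparisons. All 9 samples were random values with each gene's fitted spread, drawn independently for each gene and sample. The pipeline was tested on simulated data for each comparison, 10 simulations of 21722 genes with 200 changed. At log2 changes of 0.5, 1 and 2, it recovered 14.2%, 62.4% and 88.6% for NonV50-OKS against Mock. For 2ndV50-OKS against Mock it recovered 17.5%, 59.0% and 90.0%, and between the OKS groups 17.5%, 56.7% and 90.9%. False calls made up 5.44%, 5.73% and 5.95% of all calls in the 3 comparisons. These values were drawn independently with 1 spread per gene for all groups. They left out the unequal spread of the groups, the pairing of the OKS groups and the far larger number of genes called against Mock. The rates therefore describe the simulated setting and need not hold for the real comparisons.

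The alternatives were quantile normalization, normexp background correction, other filters on dim probes, other rules for several probes, the authors' deposited log2 values, the replicate block, the slide as a block, a fit of only the groups compared, a trended and robust prior, array weights and leaving out each sample in turn. The normexp alternative was planned on mean spot signals, which the tables do not hold, and used median spot signals with an offset of 50 instead. In the fit with array weights the estimation of the weights stopped before reaching its convergence tolerance. The slide with the array's position on it was added as a block after seeing the data. Arrays lay on 2 slides, 8 on slide 1 and 2ndV50-OKS replicate 3 alone on slide 2, so the slide block is the same as leaving out that sample.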

Results

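Gene expression was measured in 9 samples of SW480, a human colorectal adenocarcinoma cell line, with 1-colour Agilent arrays. The samples formed 3 groups of 3, named Mock, NonV50-OKS and 2ndV50-OKS. OKS is the usual shorthand for the reprogramming transcription factors OCT3/4 (gene symbol POU5F1), KLF4 and SOX2. The labels name a retrovirus as the agent and spell out neither OKS nor V50. NonV50-OKS cells came from the 1st V50-OKS cells according to the design text, so the design implies a comparison of each OKS group with Mock and of the 2 OKS groups with each other. Between 51.9% and 59.0% of the probes were well above background on each array, and 21722 genes were tested. Across genes, which are not independent replicates, the samples of a group correlated with r = 0.994 to 0.997 in Mock, 0.991 to 0.994 in NonV50-OKS and 0.981 to 0.988 in 2ndV50-OKS. OKS samples correlated with Mock samples at r = 0.936 to 0.945, and the samples of the 2 OKS groups with each other at 0.977 to 0.992.

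KLF4 rose and SOX2 fell in both OKS groups, and the 2 POU5F1 probes gave different results. KLF4, a zinc-finger transcription factor, was higher than in Mock by 2.76 ± 0.16 on the log2 scale (SE, n = 3 and 3) in each OKS group (adjusted p = 3.78e-06 in NonV50-OKS and 3.59e-06 in 2ndV50-OKS). The POU5F1 probe with the higher mean signal was 19.2-fold higher in NonV50-OKS (log2 4.27 ± 0.25, adjusted p = 4.33e-06) and 22.7-fold higher in 2ndV50-OKS (adjusted p = 3.15e-06). That probe was well above background on 1 of the 3 Mock arrays. The other POU5F1 probe was well above background on all 9 arrays and did not pass the test, with log2 differences of -0.22 ± 0.32 and -0.28 ± 0.32 (adjusted p over all probes = 0.631 and 0.525). SOX2, measured by 1 probe, was lower by -2.58 ± 0.25 in NonV50-OKS (adjusted p = 7.69e-05) and -2.17 ± 0.25 in 2ndV50-OKS (adjusted p = 0.000216). Which part of each transcript the probes read is not given in the sources used here, so these values do not separate introduced from endogenous transcripts. Between the 2 OKS groups none of the 3 genes passed limma's test (adjusted p = 0.995 for KLF4, 0.75 for POU5F1 and 0.574 for SOX2), and none had an unadjusted p under 0.05.

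**Figure D1:**
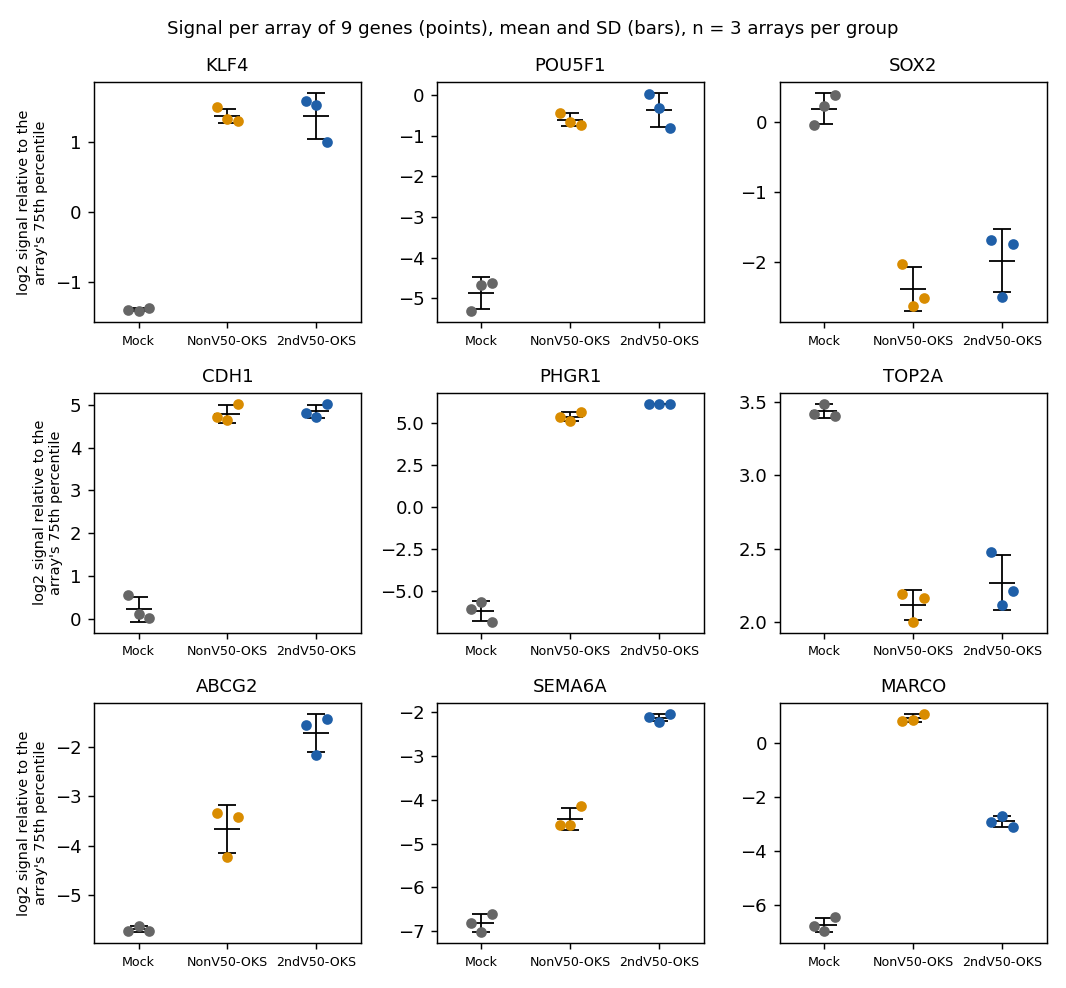
Signal of 9 genes on each array, as log2 signal relative to the array's 75th percentile (y axis, a different range in each panel), in the Mock, NonV50-OKS and 2ndV50-OKS groups (x axis), with the mean and SD of 3 arrays per group as bars. KLF4 lay at a mean of -1.39 in Mock and 1.37 and 1.36 in the OKS groups, while ABCG2 lay at -5.68 in Mock, -3.66 in NonV50-OKS and -1.72 in 2ndV50-OKS.

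The comparison of NonV50-OKS with Mock asks what distinguishes NonV50-OKS cells from the control cells. NonV50-OKS cells held far more transcript of several keratin and colonic epithelial genes. KRT6A, a keratin of stratified and wounded epithelia, was at least 5244-fold higher (adjusted p = 4.01e-07). PHGR1, a transcript of intestinal epithelium, was at least 1196-fold higher (adjusted p = 4.20e-08), and CEACAM6, a surface glycoprotein of epithelial cells, at least 167-fold. The adhesion gene CDH1, which encodes E-cadherin, was measured in both groups and rose by 4.57 ± 0.17 on the log2 scale (SE, n = 3 and 3), a 23.7-fold difference (adjusted p = 4.01e-07). LOXL2, a matrix cross-linking enzyme, was lower by -4.98 ± 0.28 (adjusted p = 3.48e-06), and TENM2, a teneurin of cell contacts, by -6.00 ± 0.22 (adjusted p = 4.01e-07). TENM2 was well above background on 1 of the 3 NonV50-OKS arrays.

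Of the 10 largest rises, the other 7 were KRT6C, SBSPON, SPON2, PDGFRB, TMPRSS4, KRT20 and LY6D, each at least 91.6-fold higher. PDGFRB, a receptor tyrosine kinase typical of mesenchymal cells, was at least 98.2-fold higher, and KRT20, a keratin of differentiated intestinal epithelium, at least 124-fold. Among the 10 largest falls were SAA1, an acute-phase protein, at -6.62 ± 0.60 (adjusted p = 5.51e-05), and MIA, a small secreted protein, at -5.58 ± 0.36 (adjusted p = 7.68e-06). GNG11, a G protein gamma subunit, was lower by -5.74 ± 0.33 (adjusted p = 4.26e-06), and NFIB, a nuclear factor I transcription factor, by -5.50 ± 0.52 (adjusted p = 6.94e-05). SAA1 and NFIB were each above background on 1 NonV50-OKS array, and GNG11 on 2. ZP1, KANK4, SAA2 and KCNJ5 completed the 10. By the rule that selected these genes, all 3 samples of the higher group lay above all 3 of the other. Probes of near-identical genes, such as KRT6A and KRT6C or SAA1 and SAA2, can share signal.

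Most of the tested colonocyte and epithelial genes rose. The colonocyte list held 28 genes. Those not tested, such as FABP1, SLC26A3, CA1 and MS4A12, were not well above background on all 3 arrays of any group. Of the 17 tested, 8 were above background on no Mock array, so they entered through OKS arrays and could hardly fall. In total 14 markers of absorptive enterocytes and colonocytes rose, none fell and 3 did not pass, with 15 higher when adjusted over the list alone (camera adjusted p = 1.94e-13, and adjusted p = 0.116 with an estimated correlation). They included CDX2, a transcription factor of intestinal identity (log2 1.51 ± 0.11), VIL1, the microvillus protein villin (1.95 ± 0.09), and HNF4A, a nuclear receptor of gut epithelium (1.92 ± 0.21). Of 27 epithelial junction and keratin genes, 21 rose, none fell and 6 did not pass, with 22 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.33e-09, and adjusted p = 0.222 with an estimated correlation). CLDN3, a tight junction claudin, rose by 1.89 ± 0.15. Of 19 squamous epithelium genes, 14 rose and 1 fell over all genes and over the list alone (camera adjusted p = 7.39e-07, and adjusted p = 0.116 with an estimated correlation), among them SPRR3, a cornified envelope protein (7.99 ± 0.41), and KLK10, a kallikrein protease (5.48 ± 0.20). KLK10 was above background on 1 Mock array and SPRR3 on 2. Of 10 goblet and secretory cell markers, 5 rose and 2 fell by both adjustments (camera adjusted p = 0.0104, and adjusted p = 0.234 with an estimated correlation). TFF3, a trefoil factor of goblet cells, rose by 4.48 ± 0.15, and MUC13, a membrane mucin, by 4.40 ± 0.16.

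Transporter and inflammatory lists were also higher. Of 14 ABC transporters of drug and lipid efflux, 9 rose and 1 fell, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000434, and adjusted p = 0.167 with an estimated correlation). ABCG1, a cholesterol exporter, rose by 2.68 ± 0.27, and ABCG2, an exporter linked to drug resistance, was at least 2.30-fold higher (adjusted p = 0.000408). Of 24 interferon-stimulated genes, 13 rose and none fell, with 14 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000434, and adjusted p = 0.436 with an estimated correlation). OAS1, an antiviral oligoadenylate synthetase, rose by 2.85 ± 0.29. Of 20 chemokine and NF-kappaB target genes, 10 rose and 1 fell, with 10 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00698, and adjusted p = 0.234 with an estimated correlation). The call ended when only probes above background on all 9 arrays were used (adjusted p = 0.0852). IL32, a cytokine, rose by 4.11 ± 0.19, and BIRC3, an inhibitor of apoptosis, by 3.34 ± 0.22.

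Most mitosis, replication and hypoxia genes fell. Of 28 mitosis genes, 27 fell and 1 did not pass, with 28 lower when adjusted over the list alone (camera adjusted p = 3.06e-10, and adjusted p = 0.436 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, fell by 1.32 ± 0.11, and FOXM1, a transcription factor of mitotic genes, by 1.31 ± 0.17. Of 28 genes of S phase and DNA replication, 20 fell and 1 rose, with 22 lower and 1 higher when adjusted over the list alone (camera adjusted p = 3.85e-05, and adjusted p = 0.569 with an estimated correlation). TYMS, thymidylate synthase, fell by 1.52 ± 0.18. Of 29 hypoxia and glycolysis genes, 25 fell and 1, BNIP3, rose by both adjustments (camera adjusted p = 1.33e-08, and adjusted p = 0.231 with an estimated correlation). ADM, a hypoxia-induced peptide hormone, fell by 2.48 ± 0.17, and CA9, a hypoxia-induced carbonic anhydrase, by 2.06 ± 0.33.

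Of the 9 genes in the metallothionein list, 8 fell and 1, the zinc exporter SLC30A1, rose by both adjustments (camera adjusted p = 0.00166, and adjusted p = 0.326 with an estimated correlation). The metal-binding proteins MT1X and MT1E fell by 1.23 ± 0.13 and 1.19 ± 0.09, although probes of near-identical metallothionein genes can share signal. In the list of the unfolded protein response and amino acid stress, 13 of 28 genes fell and none rose by both adjustments (camera adjusted p = 0.0132, and adjusted p = 0.436 with an estimated correlation). DDIT4, a stress-induced inhibitor of mTOR signalling, fell by 2.92 ± 0.30. Of 18 heat shock genes, 8 fell and 1 rose, with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0176, and adjusted p = 0.512 with an estimated correlation). HSPB1, a small heat shock protein, fell by 1.05 ± 0.15. Of 23 chromatin and DNA methylation regulators, 10 fell and 2 rose by both adjustments, EZH2, a histone methyltransferase, by -1.15 ± 0.15 (camera adjusted p = 0.0442, and adjusted p = 0.231 with an estimated correlation). That call ended without Mock replicate 1 (adjusted p = 0.0537), Mock replicate 3 (0.0591), NonV50-OKS replicate 1 (0.0604) or NonV50-OKS replicate 2 (0.0577). It also ended with quantile normalization (adjusted p = 0.0600), with only probes above background on all 9 arrays (0.0506) and with the mean of a gene's probes (0.0689).

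The stem cell, pluripotency and Wnt lists were not called. The list of intestinal and colon cancer stem cell markers held 24 genes. LGR5, PROM1, ALCAM, OLFM4 and SMOC2 were well above background on no array and were not tested. ALDH1A1 was not tested either, since it was not above background on all 3 arrays of any group. Of the 18 tested markers, 8 rose and 4 fell by both adjustments (camera adjusted p = 0.139). CD24, a surface glycoprotein, rose by 4.56 ± 0.12, and the chemokine receptor CXCR4 fell by 2.67 ± 0.10. Of 11 measured pluripotency network genes, 3 rose and 1 fell, with 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.940). NODAL, a TGF-beta family ligand, was at least 11.7-fold higher, and DNMT3B, a DNA methyltransferase, fell by 0.95 ± 0.10. Of 22 Wnt and beta-catenin target genes, 7 rose and 8 fell, with 7 higher and 10 lower when adjusted over the list alone (camera adjusted p = 0.603). DKK1, a secreted Wnt inhibitor, rose by 2.77 ± 0.21, and NKD1, an intracellular one, fell by 1.39 ± 0.20. The mesenchymal list moved both ways, with 5 of 17 higher and 6 lower by both adjustments (camera adjusted p = 0.820). Of 27 tested markers of fibroblasts, leukocytes, endothelium and erythroid cells, 8 rose and 2 fell.

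In all, 7871 of 21722 genes (36.2%) differed between NonV50-OKS and Mock with an adjusted p under 0.05 in limma, 3610 higher and 4261 lower. At least 2-fold differences were fitted for 1867 higher and 1252 lower genes. Of the 35 lists, 14 were called by camera at its preset correlation. With an estimated correlation 0 were called, 6 had an unadjusted p under 0.05, and 24 were called by fry, which does not compare a list with other genes. All arrays of these 2 groups lay on slide 1, and 8618 genes were called with slide as a block.

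The comparison of 2ndV50-OKS with Mock asks the same of the 2ndV50-OKS cells. The intestinal transcript PHGR1 and the keratin gene KRT6A were again far above Mock. PHGR1 was at least 2030-fold higher (adjusted p = 4.14e-08) and KRT6A at least 4071-fold (adjusted p = 5.02e-07). CLRN3, a clarin membrane protein, was measured in both groups and rose 356-fold (log2 8.47 ± 0.17, SE, n = 3 and 3, adjusted p = 4.14e-08). FGR, a SRC family kinase, rose 361-fold (8.50 ± 0.18, adjusted p = 4.14e-08). PRSS56, a serine protease, was lower by -7.68 ± 0.45 (adjusted p = 4.74e-06) and WNT6, a Wnt ligand, by -6.31 ± 0.41 (adjusted p = 7.71e-06).

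The other 6 of the 10 largest rises were KRT6C, SBSPON, SPON2, CEACAM6, TMPRSS4 and DPEP1, each at least 159.8-fold higher. Among the falls, IRAG1, a protein of cGMP signalling, was lower by -6.67 ± 0.41 (adjusted p = 5.94e-06), LOXL2 by -6.38 ± 0.28 (adjusted p = 8.56e-07) and CHI3L1, a chitinase-like glycoprotein, by -5.72 ± 0.27 (adjusted p = 1.35e-06). KCNJ5, a potassium channel, was lower by -7.64 ± 0.70 (adjusted p = 5.82e-05) and above background on 1 of the 3 2ndV50-OKS arrays. GNG11, SAA1, SAA2 and GRAMD1A were not well above background in 2ndV50-OKS and were lower by at least 82.3-fold, 60.9-fold, 16.5-fold and 17.1-fold. In each of these genes the 3 samples of one group lay beyond the 3 of the other. The caution on probes of near-identical genes applies here too.

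Colonocyte markers were higher in 13 of 17 tested genes and lower in none, with 14 higher when adjusted over the list alone (camera adjusted p = 8.23e-12, and adjusted p = 0.215 with an estimated correlation). The limits from untested genes and from genes that entered through OKS arrays apply here too. VIL1 rose by 2.13 ± 0.09 and HNF4A by 1.91 ± 0.21. Of 27 epithelial junction and keratin genes, 20 rose and 2 fell by both adjustments (camera adjusted p = 4.93e-07, and adjusted p = 0.249 with an estimated correlation), CDH1 by 4.62 ± 0.17. Of 19 squamous genes, 12 rose and 1 fell, with 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.6e-05, and adjusted p = 0.215 with an estimated correlation), SPRR3 by 7.49 ± 0.41. Of 10 goblet and secretory markers, 5 rose and 1 fell by both adjustments (camera adjusted p = 0.0131, and adjusted p = 0.258 with an estimated correlation), TFF3 by 5.28 ± 0.15. Of 24 interferon-stimulated genes, 11 rose and 1 fell, with 15 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000511, and adjusted p = 0.397 with an estimated correlation), OAS1 by 3.21 ± 0.29.

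Of 16 Notch pathway genes, 7 rose and 1 fell, with 10 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.243 with an estimated correlation). LFNG, a glycosyltransferase that modifies Notch, rose by 3.62 ± 0.11, HEY2, a Notch target, rose by 1.64 ± 0.12, and the receptor NOTCH2 fell by 1.07 ± 0.09. Of 14 ABC transporters, 8 rose and 3 fell, with 9 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.258 with an estimated correlation), and the call ended without 2ndV50-OKS replicate 2 (adjusted p = 0.0585) and with only probes above background on all 9 arrays (0.0766). ABCG2 was at least 8.78-fold higher (adjusted p = 8.32e-06), and ABCG1 rose by 3.28 ± 0.27. Of 25 cholesterol biosynthesis genes, 10 rose and 1 fell, with 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.617 with an estimated correlation). TM7SF2, a sterol reductase, rose by 0.92 ± 0.14, and the list's call ended without 2ndV50-OKS replicate 2 (adjusted p = 0.105) and with array weights (0.0632).

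The falls lay in the lists that were lower in NonV50-OKS. Of 28 mitosis genes, 27 fell by both adjustments (camera adjusted p = 1.31e-08, and adjusted p = 0.397 with an estimated correlation), TOP2A by -1.17 ± 0.11. Of 28 S phase genes, 15 fell and 1 rose, with 19 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000346, and adjusted p = 0.514 with an estimated correlation). Of 29 hypoxia and glycolysis genes, 25 fell and 1 rose, with 27 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.2e-08, and adjusted p = 0.243 with an estimated correlation), ADM by -3.05 ± 0.17. In the metallothionein list 8 of 9 genes fell and SLC30A1 rose by both adjustments (camera adjusted p = 8.84e-05, and adjusted p = 0.249 with an estimated correlation), MT1X by -1.89 ± 0.13. Of 28 unfolded protein response genes, 12 fell and 1 rose, with 13 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.397 with an estimated correlation). Heat shock genes fell in 11 of 18 and rose in 1, with 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.397 with an estimated correlation). Chromatin regulators fell in 9 of 23 and rose in 2, with 11 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.243 with an estimated correlation), EZH2 by -1.01 ± 0.15.

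Of the tested stem cell markers, 9 of 18 rose and 5 fell by both adjustments (camera adjusted p = 0.0942), CD24 by 4.29 ± 0.12 and CXCR4 by -2.56 ± 0.10. The limit from the untested genes of this list, such as LGR5 and PROM1, applies here too. Of 11 pluripotency genes, 3 rose and 1 fell by both adjustments (camera adjusted p = 0.275). NODAL was at least 17.4-fold higher, PODXL, a sialomucin of stem cells, rose by 1.31 ± 0.10, and TFCP2L1, a transcription factor of naive pluripotency, rose by 0.65 ± 0.09. Of 22 Wnt targets, 6 rose and 11 fell by both adjustments (camera adjusted p = 0.553), DKK4, a secreted Wnt inhibitor, by 2.22 ± 0.21. Of 20 chemokine and NF-kappaB targets, 7 rose and 3 fell, with 7 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.162). Of 27 tested markers of fibroblasts, leukocytes, endothelium and erythroid cells, 8 rose and 4 fell.

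Between 2ndV50-OKS and Mock, 7777 genes (35.8%) had an adjusted p under 0.05 in limma, 3539 higher and 4238 lower, of which 1687 and 1339 differed at least 2-fold in the fit. Of the 35 lists, 15 were called. With an estimated correlation 0 were called, 7 had an unadjusted p under 0.05, and 26 were called by fry. One 2ndV50-OKS array lay alone on slide 2, and 7255 genes were called with slide as a block and within slide 1.

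Most genes that differed from Mock did so in both OKS groups. Among them KRT6A, PHGR1, CEACAM6, KLF4 and CDH1 rose and SAA1, LOXL2 and SOX2 fell in both. In total 6399 genes changed in the same direction, 2943 higher and 3456 lower, which is 81.3% of the calls in NonV50-OKS and 82.3% of those in 2ndV50-OKS, and 10 changed in opposite directions. Independent lists of these sizes would share 588.1 higher and 831.3 lower genes. In 50 simulations of random values without change, with the same simulated control group in both comparisons, limma called 0 shared genes. With no changed genes hardly any call can arise, so that count is no measure for the 6399. The log2 fold changes correlated across genes at r = 0.933, against a simulated mean of 0.5, with a covariance of 0.985 against 0.0236. The 3 Mock arrays were too few to split, and the simulations left out the pairing of the 2 OKS groups by number. Part of the excess may therefore come from the shared controls or from that pairing.

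**Figure D2:**
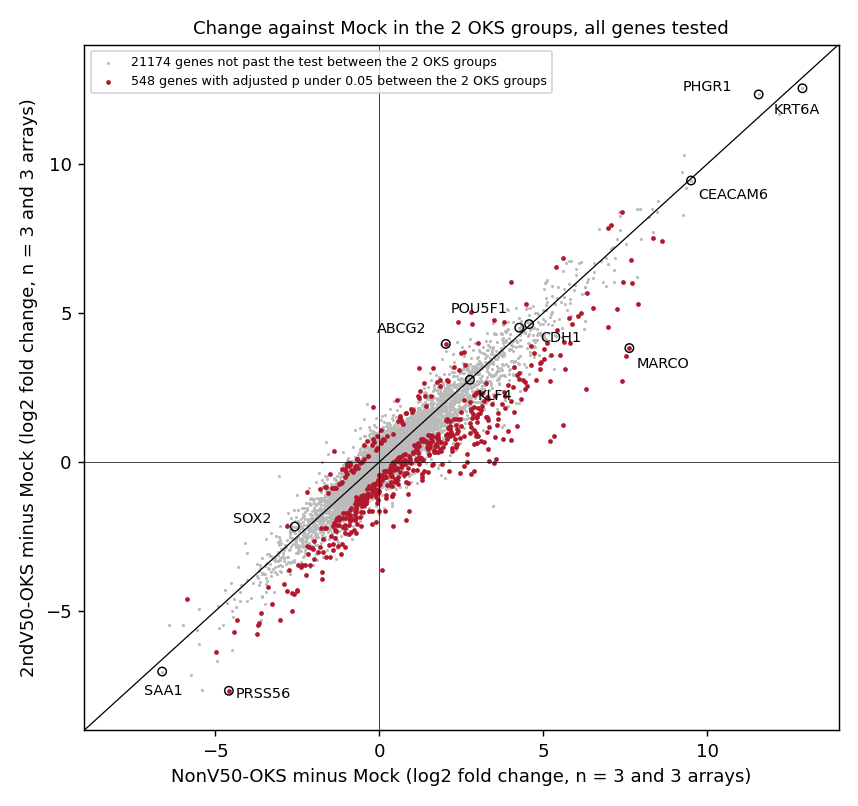
Fitted log2 fold change against Mock of the 21722 genes tested, in NonV50-OKS (x axis) and 2ndV50-OKS (y axis), from 3 arrays per group, with the diagonal of equal change. Red points are the 548 genes that differed between the 2 OKS groups, 446 of them lower and 102 higher in 2ndV50-OKS; fitted values of genes below background in Mock, such as KRT6A and PHGR1, are not bounds.

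The comparison of the 2 OKS groups asks what separates the 2ndV50-OKS cells from NonV50-OKS cells. SEMA6A, a transmembrane semaphorin, was higher in 2ndV50-OKS by 2.31 ± 0.15 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.000620), and ABCG2, the drug exporter, by 1.93 ± 0.26 (adjusted p = 0.00917). RCAN2, a regulator of calcineurin, was higher by 1.78 ± 0.13 (adjusted p = 0.000844). MARCO, a scavenger receptor, was lower by -3.80 ± 0.16 (adjusted p = 0.000108) and SPINK1, a secreted trypsin inhibitor, by -3.95 ± 0.41 (adjusted p = 0.00315). JCAD, a protein of cell junctions, was lower by -3.19 ± 0.26 (adjusted p = 0.00116).

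CDH17, the intestinal liver-intestine cadherin, and CFTR, an epithelial chloride channel, were not well above background in 2ndV50-OKS and at least 2.36-fold and 2.78-fold lower there (adjusted p = 0.00315 and 0.000844). CH25H, cholesterol 25-hydroxylase, was at least 3.54-fold lower (adjusted p = 0.000950). MYH15 and TNMD were lower by at least 3.16-fold and 3.64-fold. In each of these genes the 3 samples of one group lay beyond the 3 of the other, and the call held under every alternative in which the gene's fold was computed. With only probes above background on all 9 arrays, that was so for RCAN2 and JCAD alone. Of 40 genes that the naming rule selected and the test called, 12 kept the call under every alternative that had a value for them, and 24 of the other 28 lost it when 1 array was left out. The other called genes named for this comparison each lost the call under at least 1 alternative, most of them with no filter on dim probes. MIAT, a long noncoding RNA, was higher by 2.25 ± 0.33 (adjusted p = 0.0138) but not called without NonV50-OKS replicate 2 (adjusted p = 0.0593) or 3 (0.0598). ENTPD2, an ectonucleotidase, was higher by 1.29 ± 0.17 (adjusted p = 0.00917), and adjusted p = 0.0504 with a replicate block over the 2 OKS groups.

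The metallothionein, NF-kappaB target and immediate early lists were lower in 2ndV50-OKS. In the metallothionein list 2 of 9 genes fell and 7 fell when adjusted over the list alone (median -0.59, camera adjusted p = 6.93e-06, and adjusted p = 0.261 with an estimated correlation). MT1F was lower by -0.89 ± 0.18 (adjusted p = 0.0411), but not without any 1 array other than NonV50-OKS replicate 2 (adjusted p = 0.0603 to 0.132). MT1X was lower by -0.66 ± 0.13 (adjusted p = 0.0453), but not without any 1 array other than 2ndV50-OKS replicate 2 (adjusted p = 0.0563 to 0.150) or with a replicate block (0.0576, and 0.0510 over the 2 OKS groups). Of 20 chemokine and NF-kappaB targets 2 fell, and 9 when adjusted over the list alone (median -0.38, camera adjusted p = 0.000120, and adjusted p = 0.238 with an estimated correlation). They were TNFAIP3, an inhibitor of NF-kappaB, at -1.46 ± 0.24 (adjusted p = 0.0194) and IL32 at -0.91 ± 0.19 (adjusted p = 0.0477). The call of TNFAIP3 ended without 2ndV50-OKS replicate 1 or 3 or NonV50-OKS replicate 1 (adjusted p = 0.0595 to 0.0598) and with a replicate block over the 2 OKS groups (0.0741). The call of IL32 ended without any 1 array other than Mock replicate 3 (adjusted p = 0.0573 to 0.157). Of 31 immediate early and MAPK feedback genes 5 fell, with 10 lower and 2 higher when adjusted over the list alone (median -0.15, camera adjusted p = 0.000120, and adjusted p = 0.261 with an estimated correlation). FOS and EGR1, transcription factors induced within minutes of a stimulus, were lower by -1.10 ± 0.15 (adjusted p = 0.0108) and -0.72 ± 0.10 (adjusted p = 0.0117), and both missed the threshold with a replicate block over the 2 OKS groups (adjusted p = 0.0620 and 0.0616).

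The mesenchymal list was also lower, with 5 of 17 genes lower over all genes, and 7 lower and 1 higher when adjusted over the list alone (median -0.27, and -0.22 without the genes that have no fold, camera adjusted p = 0.00501, and adjusted p = 0.261 with an estimated correlation). VIM, the intermediate filament vimentin, was lower by -1.12 ± 0.21 (adjusted p = 0.0333), but not without any 1 array other than 2ndV50-OKS replicate 2 (adjusted p = 0.0562 to 0.112) or with a replicate block over the 2 OKS groups (0.0601). FN1, fibronectin, was below background on all 2ndV50-OKS arrays and on 1 NonV50-OKS array, which leaves no fold (adjusted p = 0.0118, and 0.0517 without NonV50-OKS replicate 1). Of 14 TGF-beta and BMP targets 2 fell and 1 rose, with 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00664, adjusted p = 0.261 with an estimated correlation, and 0.0533 without NonV50-OKS replicate 3). TGFBI, a matrix protein, fell and CCN1, a matricellular protein, rose. TGFBI (log2 -1.30 ± 0.26, adjusted p = 0.0429) and CCN1 (0.93 ± 0.17, adjusted p = 0.0322) lost their calls without any 1 array other than 2ndV50-OKS replicate 2, with adjusted p up to 0.147 and 0.115. CCN1 also lost it with a replicate block over the 2 OKS groups (adjusted p = 0.0522).

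The pluripotency list had 24 genes, of which 11 were tested. NANOG, LIN28A, LIN28B, DPPA2 and DPPA4 were not, since none was well above background on all 3 arrays of any group. Of the 11 tested genes 1 rose, and 3 when adjusted over the list alone (median 0.38, camera adjusted p = 0.00466, and adjusted p = 0.238 with an estimated correlation), and the list's call ended with no filter on dim probes (adjusted p = 0.252). The gene was PODXL, at 0.61 ± 0.10 (adjusted p = 0.0220), which was not called without Mock replicate 2, NonV50-OKS replicate 1 or 2, or 2ndV50-OKS replicate 1 or 3 (adjusted p = 0.0506 to 0.0866) or with a replicate block over the 2 OKS groups (0.0842). The 28 mitosis genes lay slightly higher as a list (median 0.16, camera adjusted p = 0.00317, and adjusted p = 0.959 with an estimated correlation). By limma 0 of them passed by either adjustment and 3 had an unadjusted p under 0.05, and the list's call ended without 2ndV50-OKS replicate 1 (adjusted p = 0.833) or NonV50-OKS replicate 2 (0.0965).

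Of 14 ABC transporters, ABCG2 rose and ABCA1, ABCC1 and ABCC3 fell, with 1 higher and 5 lower when adjusted over the list alone (median -0.12, camera adjusted p = 0.0360, and adjusted p = 0.291 with an estimated correlation). The list's call ended without NonV50-OKS replicate 2 (adjusted p = 0.361), 2ndV50-OKS replicate 1 (0.169) or replicate 3 (0.112) and with a replicate block (0.0750, and 0.134 over the 2 OKS groups) or slide and position as a block (0.263). ABCA1, a cholesterol exporter, was lower by -1.99 ± 0.35 (adjusted p = 0.0262), but not without Mock replicate 2 or any 1 OKS array other than 2ndV50-OKS replicate 2 (adjusted p = 0.0536 to 0.101) or with a replicate block (0.0567). The organic anion exporters ABCC1 (log2 -0.64 ± 0.10, adjusted p = 0.0196) and ABCC3 (-0.76 ± 0.12, adjusted p = 0.0174) lost their calls with a replicate block over the 2 OKS groups (adjusted p = 0.0625 and 0.0578). They also lost them without any 1 NonV50-OKS array or 2ndV50-OKS replicate 1, and ABCC1 without Mock replicate 2, with adjusted p up to 0.0789 and 0.0710. The squamous and lysosome lists were called lower with no gene past the test over all genes. Of 19 squamous genes none passed over all genes, 6 had an unadjusted p under 0.05 and 4 were lower when adjusted over the list alone (median -0.39, camera adjusted p = 0.0360, and adjusted p = 0.371 with an estimated correlation). That call ended with a replicate block (adjusted p = 0.0582), quantile normalization (0.0583) and only probes above background on all 9 arrays (0.449), and without 2ndV50-OKS replicate 2 (0.184), NonV50-OKS replicate 1 (0.101) or replicate 3 (0.0640). Of 25 lysosome and autophagy genes none passed by either adjustment and 1 had an unadjusted p under 0.05 (median -0.17, camera adjusted p = 0.0135, and adjusted p = 0.959 with an estimated correlation). The call ended without NonV50-OKS replicate 2 (adjusted p = 0.157) or 3 (0.0993) or 2ndV50-OKS replicate 1 (0.443) or 3 (0.164), and with slide and position as a block (0.337).

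**Figure D3:**
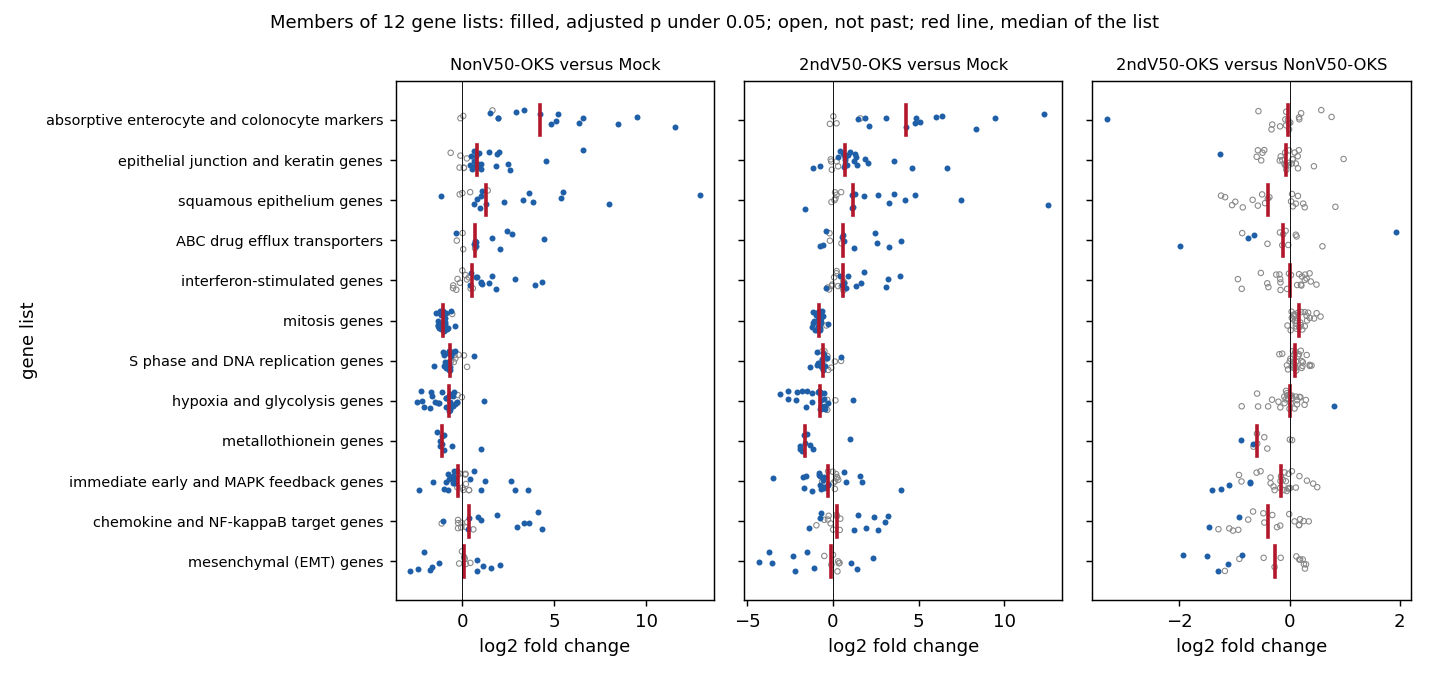
Fitted log2 fold change (x axis, a different range in each panel) of the tested members of 12 gene lists (y axis) in the 3 comparisons, with filled points for genes with an adjusted p under 0.05, open points for the others and a red line at each list's median. The mitosis list had medians of -1.03 and -0.82 against Mock and 0.16 between the OKS groups, and the metallothionein list medians of -1.08, -1.59 and -0.59.

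Colonocyte markers and Wnt targets were not called between the OKS groups. Of 17 colonocyte markers, CDH17 fell and 16 did not pass (camera adjusted p = 0.815), and of 22 Wnt targets none passed over all genes, 7 had an unadjusted p under 0.05, and 1 was higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.871). Of 18 tested stem cell markers, which do not include LGR5 or PROM1, 1 rose and 2 fell, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.815). DCLK1, a kinase of tuft and tumour stem cells, was lower by -1.20 ± 0.17 (adjusted p = 0.0115), but not called without NonV50-OKS replicate 2 (adjusted p = 0.0504) or 3 (0.0529). DPP4, a surface peptidase, was lower by -2.42 ± 0.40 (adjusted p = 0.0196), but not without any 1 NonV50-OKS array or 2ndV50-OKS replicate 3 (adjusted p = 0.0595 to 0.0797). LRIG1, a receptor of quiescent intestinal stem cells, was higher by 0.48 ± 0.09 (adjusted p = 0.0343), but not without any 1 array other than 2ndV50-OKS replicate 2 (adjusted p = 0.0580 to 0.118) or with a replicate block (0.0633, and 0.111 over the 2 OKS groups).

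In all, 548 genes (2.52%) differed between the OKS groups in limma, 102 higher and 446 lower in 2ndV50-OKS, and 2845 had an unadjusted p under 0.05. The errors behind these calls share 1 spread with the Mock arrays, whose median SD was lower (0.0987, against 0.153 in NonV50-OKS and 0.228 in 2ndV50-OKS). Of the 446 lower genes, 258 were above and 114 below Mock in NonV50-OKS, and for 95 of the 258 2ndV50-OKS did not pass the test against Mock. Of the 102 higher genes, 45 were above and 41 below Mock in NonV50-OKS, and for 24 of the 41 2ndV50-OKS did not pass. The genes were chosen with the same OKS arrays that are here set against Mock, so deviations of those arrays can shift these counts. Of the 35 lists, 10 were called at the preset correlation, 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, and 8 by fry. The gene count was 138 with no filter on dim probes, 216 in a fit of only the 2 groups, 361 with array weights, 233 with slide and position as a block, and 332 with slide as a block and within slide 1, which leaves out 2ndV50-OKS replicate 3. It was 304 without Mock replicate 2, 219, 208 and 210 without NonV50-OKS replicates 1, 2 and 3, and 295 without 2ndV50-OKS replicate 1. With replicate number as a block it was 465, and 425 over the 2 OKS groups, of which 399 and 281 were among the 548.

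Of the lists not described above, none was called in any comparison by the fit and preset correlation used throughout. Against Mock, the p53 target and CDK inhibitor list had camera adjusted p = 0.417 in NonV50-OKS and 0.184 in 2ndV50-OKS, enteroendocrine markers 0.236 and 0.174, neural genes 0.177 and 0.0951, and antigen presentation genes 0.563 and 0.232. NRF2 target and detoxification genes had 0.0585 and 0.206, oxidative phosphorylation genes 0.430 and 0.717, and cancer-testis antigen genes 0.459 and 0.541. The list of the introduced factors themselves had 0.203 and 0.174. Fibroblast markers had 0.661 and 0.826, leukocyte markers 0.149 and 0.0612, endothelial markers 0.143 and 0.0886, and erythroid markers 0.585 and 0.420. The signs of a list's median, mean and test differed for 4 lists in NonV50-OKS against Mock, 0 in 2ndV50-OKS against Mock and 7 between the OKS groups, and none of these was called.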

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

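The tests of the array on slide 2, of the numbered pairs and of the heat shock list were chosen after the results were seen, although the fit without the array on slide 2 was planned, the reading of the heat shock value was set after seeing it, and the count over other splits of the samples was chosen before. The effect against Mock differed between the 2 OKS groups for 548 genes by limma's test of the difference. In 10 genes the 2 OKS groups lay on opposite sides of Mock, each past the test. Of these, chosen after their values were seen, AMIGO2, a neuronal adhesion protein, was 0.91 above Mock in NonV50-OKS and -1.66 in 2ndV50-OKS on the log2 scale, and GALM, a sugar epimerase, was 0.81 and -0.68. The 6 NonV50-OKS and 2ndV50-OKS samples have 10 splits into 3 and 3, too few for a share under 0.05. The real split called 548 genes, 1 of the 10 splits reached that count, and the highest of the others called 0. In the other splits 316 to 3455 genes had an unadjusted p under 0.05, against 2845 in the real split. The real split parts all 3 numbered pairs. The other 3 splits that do so gave 316 to 544 genes at an unadjusted p under 0.05, and the 6 that part 1 pair gave 1287 to 3455, so the splits that keep pairs together hold a structure of the samples.

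Among the genes with the largest changes against Mock, the following differed between the OKS groups, given as 2ndV50-OKS minus NonV50-OKS on the log2 scale. PRSS56 lay at -3.09, GRAMD1A at -2.05, LOXL2 at -1.40, CHI3L1 at -1.28, PDGFRB at -1.19 and LY6D at -0.85, and KANK4 at 1.25. GRAMD1A was not above background in 2ndV50-OKS, nor KANK4 in NonV50-OKS, so these 2 values include signal near background. Of the lists called against Mock, the medians differed by -0.12 for ABC transporters, -0.39 for squamous genes, 0.16 for mitosis genes, -0.38 for chemokine and NF-kappaB targets and -0.59 for metallothioneins, each by camera at its preset correlation and none with an estimated correlation.

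The metallothionein, immediate early and NF-kappaB target lists were called lower in 2ndV50-OKS than in NonV50-OKS, with 2 of 9, 5 of 31 and 2 of 20 genes past the test, and none of the 3 was called with an estimated correlation (adjusted p = 0.261, 0.261 and 0.238). The array alone on slide 2 does not account for it, since without it the highest adjusted p of the 3 lists was 0.00165. The median difference of the 60 genes, from lists chosen because they were lower here, was -0.238, -0.264 and -0.285 in the 3 numbered pairs. The lower values therefore did not rest on 1 pair. A culture or hybridization condition shared by both samples of a pair would cancel in these differences, so they cannot test it. Handling of the cells when the groups were obtained, which may induce such early response genes, cannot be told apart from the groups, since any such step goes with the group, and the heat shock list, another early response, gave a camera adjusted p of 0.0786 (median -0.07) and of 0.0184 to 0.0480 with quantile normalization, with no filter on dim probes and without NonV50-OKS replicate 2 or 2ndV50-OKS replicate 1. A lasting difference between the 2 kinds of OKS cells stays open as well and was not tested.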

How the results depend on the processing

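The slide and position block and the replicate block over only the 2 OKS groups were chosen after seeing the data. Against Mock, gene counts stayed within 1.5 times under every alternative, at 5776 to 8629 (NonV50-OKS) and 5703 to 7798 (2ndV50-OKS) without 1 sample, and shared genes at 4627 to 6315. Between the OKS groups 548 genes became 138 with no filter on dim probes, 332 with slide as a block, 361 with array weights, 233 with slide and position as a block and 216 with only the 2 groups, and 208 to 769 without 1 sample. Of the 216 genes 191 were among the 548. Fewer samples shape the spread in the fits that leave some out. The main fit shares 1 spread over all 9 samples, although the median SD on the log2 scale was 0.0987 in Mock, 0.153 in NonV50-OKS and 0.228 in 2ndV50-OKS. The lower spread of Mock thus enters the errors between the OKS groups, and it does not in the fit of only the 2 groups. Otherwise the cause was not tested. Other alternatives gave 408 to 679. With the replicate block the counts were 8002, 7905 and 465, and 425 over the 2 OKS groups. Of the 465 genes 399 were among the 548, and of the 425 only 281, so many of the 548 calls were lost when the pairing was modelled. Of named genes and lists the block changed no call but those given beside the results, those of ADCY1, AREG, EGR2, SPATA19 and TFCP2L1 (lost) and, over the 2 OKS groups, KLK7 and the S phase list (gained, the list at adjusted p = 0.0299). Lists called fell to 0 with an estimated correlation in each comparison, and fry called 24 and 26 against Mock. Samples left out gave 13 to 15, 14 to 17 and 8 to 10 lists. Some lists gained a call under other alternatives, such as NRF2 targets (0.0459) and cholesterol genes (0.0227) in NonV50-OKS against Mock and heat shock genes (0.0477) between the OKS groups with quantile normalization, and neural genes (0.0458) in 2ndV50-OKS against Mock with normexp. POU5F1 reversed to -0.22 and -0.28 when only probes above background on all 9 arrays were used, because the other probe then stands for the gene. Of 1684 values of named genes in NonV50-OKS against Mock 12 lost the call, of 1790 in 2ndV50-OKS against Mock 22, and of 1075 between the OKS groups 232, with 17 gained. Signal near background limits folds: 508 and 430 of the genes higher than Mock have only a bound.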

Other observations

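Apart from the counts over other splits and the neighbouring-gene test, the tests here were chosen after the results were seen, although the fits with quantile normalization and normexp that the scaling test reads were planned. Gene families, also tested after, were grouped by symbol stem over all 253 families of at least 8 tested genes, and 13 and 15 of them were called against Mock, of which some are given here. A stem is the part of a symbol before its first digit, so a family can hold genes that only share the stem. Small proline-rich proteins of the SPRR family, components of the cornified envelope, rose in 7 of 8 genes in each OKS group (medians 4.80 and 3.77 on the log2 scale, fitted values that include genes near background, camera adjusted p = 0.000134 and 0.000450). CEACAM adhesion molecules rose in 6 of 9 in each (adjusted p = 0.000643 and 0.000686), kallikrein proteases of the KLK family in 9 and 7 of 11 (0.000643 and 0.00903), and tetraspanin membrane proteins of the TSPAN family in 11 and 12 of 18, with 2 and 3 lower (0.00289 and 0.00360). MCM genes, which include the replicative helicase, fell in 10 and 8 of 11 (0.00766 and 0.0188), and nucleoporins of the NUP family in 15 and 12 of 23, with 1 higher in each (0.0319 and 0.0300). Genes of the HOXA stem, which include those that pattern the body axis, fell in 9 of 12 with 1 higher in each OKS group (0.0366 and 0.0334), but missed the threshold under quantile normalization (0.0550 and 0.0502). Each of these directions was the same under quantile normalization and normexp. It was also the same with the authors' values, which are scaled almost as the main ones and are no separate check. None of the families was called with an estimated correlation (lowest adjusted p = 0.964 and 0.968), and probes of near-identical members can share signal.

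Between the OKS groups 6 families were called. The annexins, calcium-dependent membrane-binding proteins, were lower in 4 of 15 genes (camera adjusted p = 0.00420) and the ABCC transporters in 3 of 9 (0.000389) in 2ndV50-OKS. So were the MT family of metallothioneins in 3 of 11 (0.000389) and genes of the WNT stem, which include the Wnt ligands, in 2 of 13 (0.0294). Genes of the ITGB stem, which include integrin subunits, were lower in 1 of 10 (0.0283). KRTAP genes of hair keratin-associated proteins were called higher (0.0283), with 1 of 43 higher and 1 lower past the test. All 6 had the same direction under quantile normalization and normexp. With an estimated correlation the lowest adjusted p of any family was 0.827.

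More than 1 in 3 genes differed between Mock and both OKS groups (7871 and 7777 genes), 10 splits are too few for a share under 0.05, and 1 of 10 splits reached the real count in each comparison, with 0 genes by limma in the highest of the others and up to 346 and 888 genes at an unadjusted p under 0.05. The choice among the scalings and background corrections tried does not account for it, since the lowest count under quantile normalization and normexp was 7827. The median of all genes moved by at most 0.0329. Each of these settings brings the arrays to a common level, so a shift of most genes at once could not be seen. The rise of intestinal epithelial genes (14 and 13 of 17 tested colonocyte markers, none lower) was known before stromal or blood cells were considered, so it is no separate test. Its median was at least 3.43, with genes near background at their bound and genes without a fold left out. Stromal or blood cells would dilute epithelial transcripts, so such cells would not by themselves give this rise. For the other genes they stay open, since 29.6% of 27 tested markers rose in each OKS group against 16.6% and 16.3% of all genes (8 markers, PDGFRB by at least 98.2-fold in NonV50-OKS), and the leukocyte list (adjusted p = 0.0381 to 0.0454) and the endothelial list (0.0107 to 0.0469) were called higher against Mock under some alternatives, although COL1A2 and COL3A1 were not above background on all arrays of any group. Neighbouring genes moved together more than in shuffled gene orders, with a ratio of the spread of medians of 50 genes of 1.46 and 1.49 against Mock and 1.3 between the OKS groups (permutation p = 0.001 for each, the smallest that 1000 shuffles can give), so a copy-number difference between the cell populations may add to the pattern, though co-regulated neighbours would give the same and the medians of the 284 blocks stayed between -0.382 and 0.378; the OKS treatment itself stays open.

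The probes of the introduced factors did not move together, since KLF4 and 1 POU5F1 probe rose and SOX2 fell in both OKS groups. The 2 POU5F1 probes differed by 4.49 ± 0.40 in their change against Mock, 11.2 times the SE, so the probes may read different transcripts or parts of a transcript. For SOX2, with 1 probe, this could not be tested, and whether it reads the introduced transcript stays open.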
